A study of Mus musculus with 35 samples.

How the data were processed

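Of the 35 samples, 8 mRNA and 18 miRNA libraries entered the analysis through the processed values the authors deposited, and the 9 Argonaute HITS-CLIP samples (3 eWAT, 6 iBAT) were not analysed here. Groups were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns, mRNA libraries were made with a stranded total RNA kit and sequenced on a NextSeq 500, and miRNA libraries were made with a small RNA kit. The submitters' processing notes name kallisto 0.45.0, DESeq2, DESeq, Novoalign, mm10 and GRCm38 without saying which served which assay. The aligner and counter of the miRNA reads are not given in the sources used here.

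The mRNA file holds only the authors' comparison of iBAT with eWAT for 18947 genes, of which 18758 have a symbol and 189 do not. Its base mean is a signal value per gene, a mean over all samples of counts divided by size factors, per the file headers. Its log2 fold changes and their standard errors are log2 values the authors made, per the file headers. Its p-values and adjusted p-values are those the authors deposited; Benjamini-Hochberg adjustment of the p-values gave the adjusted ones within 2.4e-07. The p-value equalled that of fold change over SE within 0.01 on the log10 scale for 10.7% of genes. For most genes the p-value therefore does not follow from the SE printed beside it. The test behind the p-values is not given in the sources used here. The calls use the deposited p-values as they stand. The header does not state the direction. Ucp1 and Cidea were positive and Wt1 and Lep negative, so positive values were read as higher in iBAT. No mRNA value per library was at hand, so no SD, n or test of these libraries could be computed, and the rule that the groups must not overlap was not applied to mRNA genes.

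The miRNA file holds normalized counts for 485 miRNAs in 18 columns, a signal the authors deposited after dividing counts by size factors per library. It also holds log2 fold changes with standard errors, their ratio as a test statistic (a score the authors deposited), p-values and adjusted p-values for 6 comparisons of the authors. Whole reads were recovered from the normalized values, with 100% of values in each column whole within 0.02 reads. In 6 libraries the smallest value was 1 read, which fixes the unit, and in 12 libraries it was 2 reads. Only 6 values in all were of exactly 1 read, beside 258 of 2 and 137 of 3. A value of 0 may therefore stand for a single read. Recovered totals ranged from 1293407 to 6816555. Before the data were examined, the design had planned edgeR for raw counts and limma for normalized values; the values were normalized, so limma was the main test and count tests on recovered reads were added.

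The main miRNA test was limma 3.58.1 (R 4.3.3), with eBayes and a mean-variance trend on log2(normalized count + 1), all 6 depots in 1 fit with 12 residual degrees of freedom. A miRNA was tested if edgeR's filterByExpr kept its recovered reads, which left 436 of 485 and removed 49. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each of the 15 pairs of depots, and an F test covered all depots. A miRNA was counted apart in iBAT when all 5 comparisons with white depots were called with 1 sign. Standard errors come from the fit, means and SDs from the normalized counts. Where all 3 libraries of a depot were at 0, folds were computed against a floor of 3 reads per library and are lower bounds; such floors and intervals cover counting error only. Placing the members at 0 at their bound moved no list median (2 members of the epithelial list, 1 of the Hox-cluster list and 1 of the miR-17-92 list).

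Gene lists and miRNA lists were fixed before the data were examined. The 20 gene lists covered brown adipocyte, white adipocyte and shared adipocyte genes, visceral and mesothelial genes, Hox genes, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, lipogenesis, macrophage, lymphocyte, endothelial, fibroblast, smooth muscle, skeletal muscle, epididymis, Schwann cell and red blood cell markers, miR-29 targets among matrix genes, and the miRNA pathway. They were tested with limma's cameraPR (correlation 0.01) on signed z values from the deposited p-values, a test chosen after seeing that no values per library were at hand. The 15 miRNA lists covered brown fat, opposition to browning, muscle, Hox clusters, immune cells, endothelium, mesenchyme, red blood cells, epithelium, liver and nerve, let-7, miR-29, miR-30, miR-17-92 and Dlk1-Dio3. Those with at least 3 tested members (14 of them) were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, which asks whether members move 1 way on balance and does not compare a list with other miRNAs. With an estimated correlation only the call of the brown fat list held.

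Genes were named by a rule fixed before the data were examined. For mRNA it takes the 10 largest log2 fold changes in each direction among called genes with above-median base mean, up to 4 members of each list with the smallest p, and Ucp1, Lep, Adipoq and the 4 Argonaute genes; 2 list members it picks are not reported here. For miRNA it takes the 8 largest in each direction among called, above-median miRNAs whose groups do not overlap, up to 3 members of each list with the smallest p, 3 members of the miR-29 family, the 6 smallest p over all depots, the 5 smallest p for cWAT against iWAT and the 5 most abundant of each depot. Outside the rule, miR-30b-5p, miR-150-5p, miR-192-5p, miR-194-5p, miR-215-5p, miR-375-3p, miR-142a-3p, miR-362-5p, the miRNAs lower in iBAT than in all white depots, and the host pairs of miR-455-3p, miR-455-5p, miR-582-3p, Nfyc, Pank1 and Wwp2 were named after their values were seen.

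Host genes of 66 miRNA and gene pairs were fixed before the data were examined, and 63 of the 64 pairs with coordinates lie inside the RefSeq span of the host on GRCm38. Correlations used 1 value per host gene and two-sided permutation tests with 100000 resamples (SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, Python 3.11.15). Coordinates come from the RefSeq gene table of GRCm38. How reads that fit several members of a family, such as let-7 or miR-378, were counted is not given in the sources used here. No genome was used, so the planned test of seed sites was not run.

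The alternatives were other scalings (quantile normalization, median centring, equal totals, equal totals without the 5 most abundant miRNAs), pseudocounts of 0.5 and 5, no trend, no filter, a mean of at least 10 in 1 depot, limma treat at 2-fold, a block for the replicate number, only the iBAT and eWAT libraries, and leaving out each library. Added after seeing the data were edgeR 4.0.16 (TMM, RLE, and with the block) and DESeq2 1.42.0 on recovered reads, which called 228 and 231 miRNAs for iBAT against eWAT, 226 of each shared with limma, and leaving out iWAT 3 and cWAT 2 together. On simulated data (436 miRNAs, 200 changed, 5 draws, iBAT against eWAT) limma recovered 66.4% of 2-fold and 85.6% of 4-fold changes with 1.6% false calls, edgeR 68.4% and 87.2% with 1.8%. The simulated changes were equal in number in both directions and lay in iBAT alone, so these shares do not cover errors of scaling. With independent simulated scores for 18947 genes, 3.8% of 1000 random lists of 20 genes had a cameraPR p under 0.05. Those scores held no correlation between genes, so this does not test the preset correlation. Pairs of libraries of 1 depot were checked for duplicates, and none matched within sampling noise (chi-square per degree of freedom 29.5 to 1137.6). Figures were drawn with matplotlib 3.10.9.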

Results

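Mouse fat depots were profiled with 3 sequencing assays in 35 samples. Argonaute HITS-CLIP, which sequences RNA crosslinked to the Argonaute proteins that carry microRNAs, covered 6 samples of interscapular brown fat (iBAT) and 3 of epididymal white fat (eWAT) at 15 weeks of age, each made from 2 pooled mice. Those 9 samples were not analysed here. Messenger RNA was sequenced from 4 iBAT and 4 eWAT samples of the same age. MicroRNA (miRNA) was sequenced from male C57BL/6J mice of 13 weeks in 3 libraries from each of 6 depots, labelled iBAT, eWAT, mWAT, iWAT, aWAT and cWAT. The names mWAT, iWAT, aWAT and cWAT are kept as the labels write them. The protocol text also mentions cold housing (4 °C, 1 week) of mice whose inguinal pads were taken, without tying it to a depot label, so housing temperature was not used to define any group. No label spells out cWAT, which may be that inguinal fat rather than a depot of its own, so that the groups counted as 6 depots, 5 of them white, may be 1 fewer. No label states that the mRNA or miRNA libraries came from separate animals, and the p-values then measure only the spread between these samples.

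The reads counted to miRNAs numbered 1293407, 3329370 and 1662312 in iBAT 1 to 3, and 4122136, 5694349 and 4200661 in eWAT. They numbered 2817527, 1943300 and 2871504 in mWAT, 3776278, 1887790 and 2245145 in iWAT, 2535190, 1791767 and 1815943 in aWAT, and 2452236, 1449708 and 6816555 in cWAT. The totals spanned 5.27-fold. The mRNA file gave the authors' comparison of iBAT with eWAT for 18947 genes, with a median base mean of 342.8, and the depth of single mRNA libraries is unknown.

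The mRNA comparison asked which genes separate brown from epididymal white fat. Ucp1 (ENSMUSG00000031710, GRCm38 chromosome 8, 83290348 to 83298456), the mitochondrial uncoupling protein of brown adipocytes, was higher in iBAT by a log2 fold change of 15.87 ± 0.90 (SE) with an adjusted p of 8.46e-69 in the authors' deposited table. Cidea (ENSMUSG00000024526), a lipid droplet protein, was higher by 9.58 ± 0.13 with its p listed at 0 in the authors' deposited table. Lep (ENSMUSG00000059201), which encodes leptin, was lower in iBAT at -2.77 ± 0.84 (adjusted p = 0.000326), and Adipoq (ENSMUSG00000022878), which encodes adiponectin, was lower at -1.48 ± 0.28 (adjusted p = 1.85e-07) in the authors' deposited table. The direction of the authors' deposited table was read from Ucp1, Cidea, Wt1 and Lep, so these genes are not independent evidence of it. Errors on log2 fold changes are standard errors throughout.

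At an adjusted p under 0.05, 9100 of the 18947 genes (48%) were called in the authors' deposited table, 3965 higher in iBAT and 5135 lower. Among them 5790 differed by at least 1 on the log2 scale, with 2093 higher and 3697 lower in the authors' deposited table. The median log2 fold change over all genes was -0.10, and when fold changes were centred on it, with p-values taken from fold change over SE, the balance turned to 4246 higher and 4008 lower among 8254 calls.

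Genes of brown adipocytes and thermogenesis formed the list furthest toward iBAT among those of adipocytes. Of 38 measured members, 32 were higher in iBAT, 3 lower and 3 not called in the authors' deposited table, with a median log2 fold change of 4.62 (limma cameraPR with Benjamini-Hochberg adjustment, adjusted p = 1.06e-58). They included Cox8b, a cytochrome c oxidase subunit (7.90 ± 0.17, p listed at 0), Cpt1b, which moves fatty acids into mitochondria (9.26 ± 0.18, p listed at 0), and Ppara, a nuclear receptor of fatty acid metabolism (5.52 ± 0.17, adjusted p = 4.11e-217), in the authors' deposited table. The members lower in iBAT were Cited1 (-4.99), Ckmt1 (-2.74) and the beta-3 adrenergic receptor gene Adrb3 (-1.23) in the authors' deposited table. Skeletal muscle markers were higher in iBAT too, as given below, and how far muscle shares in the values of this list was not tested. The list of white adipocyte and adipokine genes had 17 of 22 members lower in iBAT, 1 higher and 4 not called, with a median of -2.97 (cameraPR adjusted p = 1.59e-08, from the authors' deposited table). Its members lower in iBAT included Agt, which encodes angiotensinogen (-5.93 ± 0.24, adjusted p = 1.1e-129), the amino acid transporter Slc7a10 (-4.18 ± 0.36, adjusted p = 5.78e-31) and Hoxc8 (-3.54 ± 0.30, adjusted p = 6.3e-31) in the authors' deposited table. The exception, Nampt, an enzyme of NAD synthesis, was higher in iBAT at 2.21 ± 0.19 (adjusted p = 1.38e-29) in the authors' deposited table.

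Genes used by both kinds of adipocyte moved in both directions. Of 20 members 6 were higher in iBAT, 6 lower and 8 not called in the authors' deposited table, and the list did not pass (cameraPR adjusted p = 0.364). The median was -0.01, while the mean of 0.09 and the test pointed toward iBAT. Gpd1, an enzyme of glycerol phosphate synthesis (4.14 ± 0.22, adjusted p = 8.23e-76), Dgat2, an enzyme of triglyceride synthesis (2.05 ± 0.26, adjusted p = 6.35e-15), and the glucose transporter gene Slc2a4 (1.63 ± 0.21, adjusted p = 7.28e-14) were higher in iBAT in the authors' deposited table. Cfd, which encodes the adipokine adipsin, was lower at -2.84 ± 0.31 (adjusted p = 2.32e-19) in the authors' deposited table.

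Mitochondrial energy metabolism was higher in iBAT in each of its 3 lists. Of their members 4 (oxidative phosphorylation), 5 (tricarboxylic acid cycle) and 3 (fatty acid oxidation) also belong to other lists, so the lists are not separate evidence. Of 75 measured oxidative phosphorylation genes, 72 were higher and 1 lower, with a median of 1.86 (cameraPR adjusted p = 1.48e-36, from the authors' deposited table). The electron carrier gene Cycs (3.07 ± 0.13, adjusted p = 2.75e-119), the complex III gene Uqcrc2 (2.80 ± 0.14), the complex II gene Sdha (2.79 ± 0.15) and the complex I gene Ndufa9 (2.40 ± 0.12) were among them in the authors' deposited table. In the tricarboxylic acid cycle 20 of 21 genes were higher and 1 was not called (median 2.88, cameraPR adjusted p = 4.46e-52, from the authors' deposited table), among them the succinyl-CoA ligase genes Sucla2 (4.42 ± 0.12, adjusted p = 8.2e-270) and Suclg1 (3.62 ± 0.15), and Ogdh (3.75 ± 0.15). Mitochondrial fatty acid oxidation had 20 of 21 members higher, including the dehydrogenase genes Acadl (3.84 ± 0.16, adjusted p = 2.03e-123) and Acadm (3.31 ± 0.16) and the trifunctional protein gene Hadhb (4.05 ± 0.18), and Cpt1a was lower at -1.90 in the authors' deposited table (median 2.42, cameraPR adjusted p = 1.99e-37). De novo lipogenesis genes were higher in 12 of 15 cases and never lower (median 1.44, cameraPR adjusted p = 0.000106, from the authors' deposited table). Elovl6, a fatty acid elongase (4.64 ± 0.48), Acacb, an acetyl-CoA carboxylase (3.17 ± 0.31), and the transcription factor genes Mlxipl (2.20 ± 0.21, adjusted p = 3.78e-25) and Srebf1 (0.98 ± 0.13) were among them in the authors' deposited table.

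Skeletal muscle markers moved with the brown and mitochondrial lists. All 22 measured muscle markers were higher in iBAT, with a median of 6.39 (cameraPR adjusted p = 1.96e-53, from the authors' deposited table). Myh4, a fast myosin heavy chain (ENSMUSG00000057003, base mean 23670), stood at 17.69 ± 1.36 (adjusted p = 3.81e-61), the muscle calcium pump gene Atp2a1 at 11.47 ± 0.31 (p listed at 0) and the fast troponin gene Tnnt3 at 9.75 ± 0.26 (adjusted p = 5.17e-301) in the authors' deposited table. The calcium-binding protein gene Pvalb (8.99 ± 0.35), the sarcomere gene Tcap (8.97 ± 0.37) and the slow myosin gene Myh7 (9.62 ± 0.51, adjusted p = 4.48e-78) were also higher in iBAT in the authors' deposited table. Other genes with the largest fold changes toward iBAT, among those of above-median base mean, were Xirp2 (17.13 ± 3.48), the mitochondrial creatine kinase gene Ckmt2 (12 ± 0.98), Ampd1, the AMP deaminase of muscle (11.50 ± 1.32), Cpn2 (10.75 ± 0.51) and the fatty acid elongase gene Elovl3 (9.76 ± 1.60) in the authors' deposited table.

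Genes of the mesothelium and of visceral development were lower in iBAT, 20 of 22 measured with a median of -6.11 (cameraPR adjusted p = 2.39e-26, from the authors' deposited table). Rspo1, a secreted Wnt modulator (-6.41 ± 0.30, adjusted p = 8.39e-98), Gpm6a (-5.81 ± 0.28), Aldh1a2, a retinoic acid synthesis enzyme (-5.08 ± 0.25), and the keratin gene Krt19 (-8.47 ± 0.50) were among them in the authors' deposited table. Markers of the epididymis moved the same way, with 15 of 19 lower in iBAT and 4 not called (median -7.75, cameraPR adjusted p = 4.02e-05, from the authors' deposited table). The epididymal secretory genes Lcn5 (ENSMUSG00000026937, -17.81 ± 4.24, adjusted p = 1.42e-13), Crisp1 (-14.34 ± 1.72, adjusted p = 5.86e-17) and Rnase9 (-16.71 ± 4.26) were lower in iBAT, as were Adam7 (-16.91 ± 4.17) and Spint4 (-15.17 ± 4.16), in the authors' deposited table. Cuzd1 (-10.83 ± 1.23) and Clu (-3.85 ± 0.51) of the same list were lower too, and so were the epithelial genes Epcam (-14.13 ± 3.54), Krt8 (-15.22 ± 3.51), Prom2 (-15.04 ± 3.96) and Upk1b (-14.21 ± 3.36) in the authors' deposited table. Akr1b7, an aldo-keto reductase, was lower at -13.95 ± 1.19 with a base mean of 51460 in the authors' deposited table. The standard errors of 3 to 4 beside several of these values are large for the table, and no values of single libraries were at hand to show whether a tissue was at 0. The deposited p-values of such genes, Lcn5 and Krt8 among them, are far smaller than fold change over SE would give. With p-values from fold change over SE the epididymis list still passed (cameraPR adjusted p = 0.00204).

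Hox genes, which mark position along the body axis, were lower in iBAT in 21 of 35 measured cases, higher in 4 and not called in 10 (median -1.2, cameraPR adjusted p = 0.00436, from the authors' deposited table). Hoxc9 fell by 5.40 ± 0.53 on the log2 scale (adjusted p = 8.92e-24), while Hoxa4 (2.19 ± 0.19, adjusted p = 2.29e-29) and Hoxa5 (1.68 ± 0.17, adjusted p = 3.14e-23) were higher in iBAT in the authors' deposited table. This list and that of white adipocyte genes have 3 members in common.

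Immune and stromal markers were lower in iBAT. Of 21 macrophage markers 20 were lower (median -2.08, cameraPR adjusted p = 9.74e-13, from the authors' deposited table), among them the elastase gene Mmp12 (-4.19 ± 0.27, adjusted p = 1.74e-53), Cd9 (-2.12 ± 0.20), the growth factor receptor gene Csf1r (-1.84 ± 0.14) and Mrc1 (-1.61 ± 0.16). Of 21 lymphocyte markers 12 were lower and 9 not called (median -1.50, cameraPR adjusted p = 0.00436, from the authors' deposited table), including the immunoglobulin genes Igkc (-4.82 ± 0.39) and Ighm (-3.75 ± 0.30, adjusted p = 8.93e-35) and the T cell genes Cd2 (-2.87 ± 0.43) and Cd3g (-1.97 ± 0.40). Fibroblast and adipose progenitor markers were lower in 16 of 18 cases (median -1.35, cameraPR adjusted p = 1.93e-08, from the authors' deposited table), among them the proteoglycan gene Dcn (-2.18 ± 0.16, adjusted p = 4.32e-42), with Pdpn (-2.92 ± 0.31), Col6a1 (-1.44 ± 0.12) and Fstl1 (-1.18 ± 0.11). Collagen and matrix genes described as miR-29 targets were lower in 16 of 22 cases and higher in none (median -1.10, cameraPR adjusted p = 8.11e-06, from the authors' deposited table), and this call was lost when fold changes replaced signed z values (adjusted p = 0.214). This list and that of fibroblast markers have 2 members in common. Elastin, Eln, was lower at -2.28 ± 0.20 (adjusted p = 1.98e-29), with Adamts2 (-1.82 ± 0.20), Col5a3 (-1.44 ± 0.15) and Col5a2 (-1.13 ± 0.12), in the authors' deposited table.

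Vascular, nerve and blood markers gave mixed results. Endothelial markers (3 higher, 5 lower, 8 not called of 16; median -0.24, cameraPR adjusted p = 0.66) held Plvap, a protein of vessel fenestrae (-2 ± 0.16, adjusted p = 4.87e-36), and Cldn5 (-1.56 ± 0.31) against the receptor genes Kdr (1.11 ± 0.22) and Tie1 (0.65 ± 0.16) in the authors' deposited table. Smooth muscle and pericyte markers split into 6 higher and 7 lower of 14 (median -0.68, cameraPR adjusted p = 0.726), with Cspg4 (2.96 ± 0.40) and Rgs5 (1.40 ± 0.18) higher and Tagln (-2.84 ± 0.40) and Acta2 (-2.81 ± 0.46) lower in the authors' deposited table. Schwann cell and nerve markers were higher in 8 of 15 cases and lower in 2 (median 1.35, cameraPR adjusted p = 0.0087), with S100b (5.67 ± 0.35, adjusted p = 1.68e-58) and the myelin gene Mbp (1.22 ± 0.11) higher and Pmp22 lower (-0.94 ± 0.21) in the authors' deposited table. Red blood cell markers did not pass as a list (1 higher, 2 lower of 10; median -0.41, cameraPR adjusted p = 0.66): Epb42 was higher (1.74 ± 0.62, adjusted p = 0.00255), Hba-a1 lower (-0.86 ± 0.32, adjusted p = 0.0106), and Hbb-bt was not called (-0.45 ± 0.25, adjusted p = 0.12) in the authors' deposited table. Hba-a2, a near copy of Hba-a1 with which it may share reads, was lower at -0.63 ± 0.29 (adjusted p = 0.0458) in the authors' deposited table, and this call was lost with p-values from fold change over SE (adjusted p = 0.0617).

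The miRNA pathway itself showed few calls, 6 of 20 genes higher in iBAT and 1 lower (median 0.32, cameraPR adjusted p = 0.128, from the authors' deposited table, and 0.0169 with ranks). Ago2, the Argonaute protein able to cleave its target RNA (ENSMUSG00000036698, 1.51 ± 0.27, adjusted p = 8.66e-08), Ago3 (0.79 ± 0.15, adjusted p = 5.4e-07), the helicase gene Ddx17 (0.91 ± 0.16) and the silencing scaffold gene Tnrc6b (1.19 ± 0.27) were higher in iBAT in the authors' deposited table. Ago1 (0.42 ± 0.25, adjusted p = 0.151) and Ago4 (0.32 ± 0.18, adjusted p = 0.142) were not called in the authors' deposited table. Counts adjusted over the list alone equalled those over all genes in 16 of the 20 lists. In the other 4 lists, the counts adjusted over the list alone were 33 higher and 3 lower (brown adipocyte), 7 and 6 (shared adipocyte), 7 and 7 (smooth muscle), and 1 and 1 (red blood cell). In total 15 of the 20 lists passed. Their p-values rest on the preset correlation of 0.01 between genes, which could not be estimated without values per library. They may be too small where the genes of a list vary together. Among the miRNA lists below, where the correlation could be estimated, only the brown fat list kept its camera call.

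**Figure D1:**
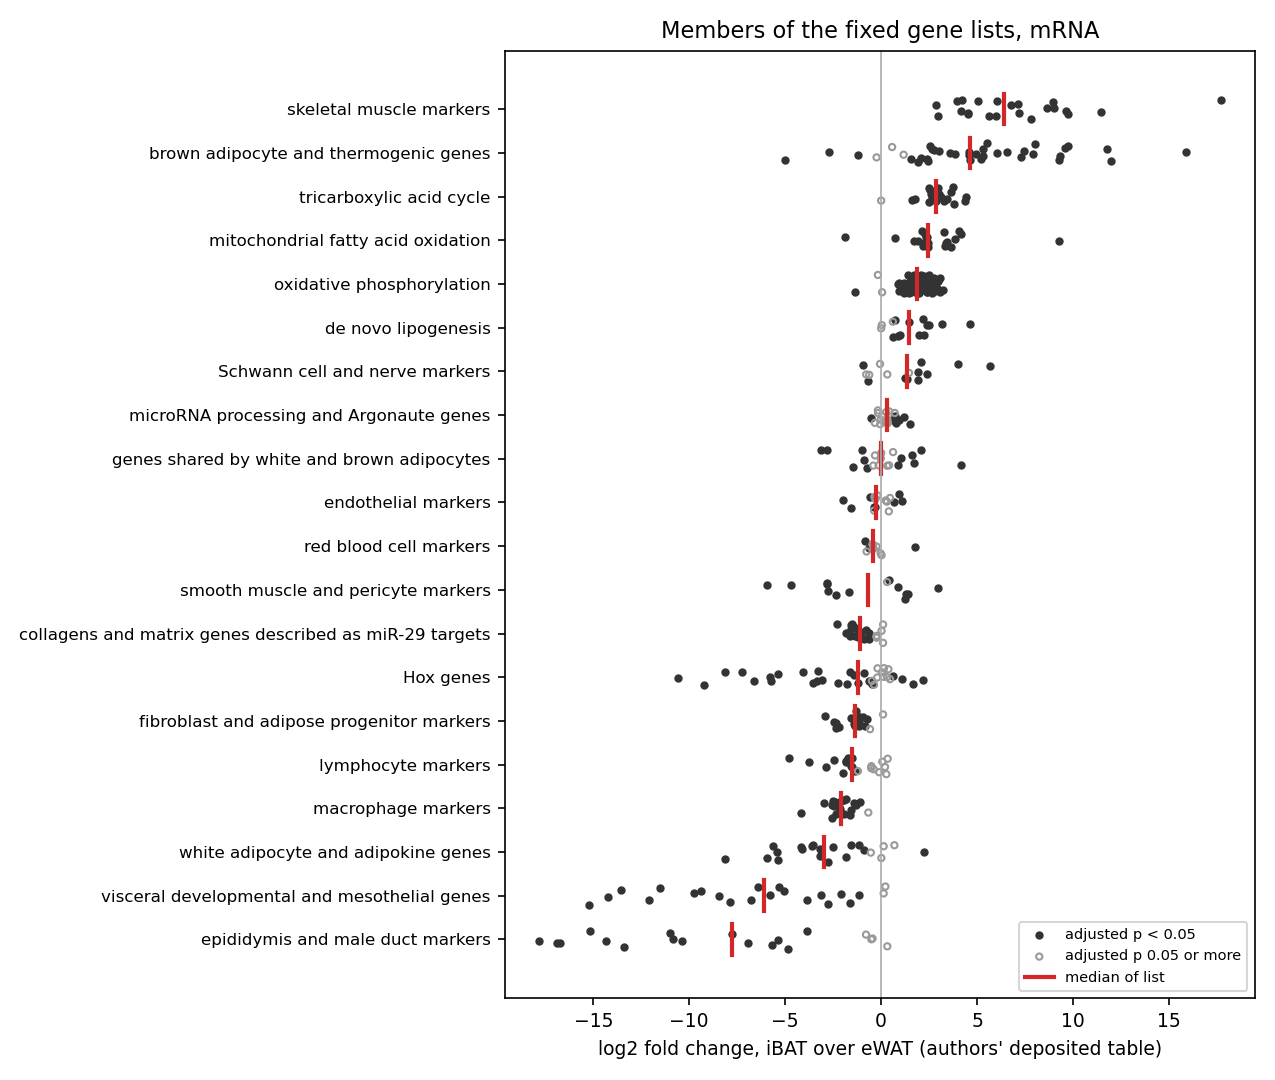
Each point is 1 gene of the 20 fixed lists, placed by the log2 fold change of iBAT over eWAT in the authors' deposited table (filled where the adjusted p is under 0.05), with the list median as a red mark. The skeletal muscle list has the highest median (6.39) and the epididymis list the lowest (-7.75).

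Between the same depots, the miRNA libraries asked which mature miRNAs separate brown from epididymal white fat. miR-378a-3p was 14.4-fold higher in iBAT, at 225950 ± 22687 normalized counts (SD, n = 3) against 15630 ± 780 (SD, n = 3), and took 7.56% of all normalized counts there against 0.62% in eWAT (limma with Benjamini-Hochberg adjustment, adjusted p = 2.1e-10). miR-30e-5p was 6.74-fold higher, at 222340 ± 17268 against 32931 ± 689 (SD, n = 3 each; limma adjusted p = 1e-10). miR-182-5p was 74.9-fold higher, at 12729 ± 2143 against 175.8 ± 62.1 (SD, n = 3 each; limma adjusted p = 2e-06). In the other direction miR-34c-5p was 44-fold higher in eWAT, at 7688 ± 3510 against 162.2 ± 33.8 (SD, n = 3 each; limma adjusted p = 1.7e-08). Folds are on the scale of log2(normalized count + 1), which understates changes of scarce miRNAs.

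Of 436 miRNAs tested, 240 differed between iBAT and eWAT, 111 higher in iBAT and 129 lower, and 263 had an unadjusted p under 0.05. At least 2-fold differences were seen for 135 of the 240, 58 higher and 77 lower. The 3 libraries of each depot did not overlap for 302 miRNAs, where chance alone gives 10% of those tested. The balance of directions depended on the scaling. It was 46.2% higher in iBAT with the authors' size factors, when the median of all miRNAs stood at -0.14. Scaling to equal library totals moved that median to -0.36 and the split to 80 higher and 160 lower (33.3% higher), and leaving the 5 most abundant miRNAs out of the totals moved them to -0.56 and to 58 and 194 (23%). Centring each library on its median turned the balance the other way, to 55.5% higher in iBAT. For the same comparison, 235 miRNAs in the authors' deposited table had an adjusted p under 0.05, and of these 225 were also called here.

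Besides those above, the largest changes toward iBAT among miRNAs of above-median abundance were in the cluster of miR-182, miR-96 and miR-183, in the miR-378 family and in the muscle miRNAs. miR-96-5p had a log2 fold change of 4.76 ± 0.66 (3139 ± 1271 against 116.4 ± 53.7, SD, n = 3 each; limma adjusted p = 2.4e-05), and miR-183-5p of 4.39 ± 0.58 (limma adjusted p = 1.3e-05). The genes of this cluster lie on GRCm38 chromosome 6, with Mir182 at 30165918 to 30165992 and Mir96 and Mir183 between 30169446 and 30169737. miR-378c (4.13 ± 0.26) and miR-378a-5p (4.11 ± 0.26) changed like miR-378a-3p (3.85 ± 0.19), and the near-identical members of the miR-378 family may share reads. The muscle miRNAs miR-133a-3p (3.98 ± 1.22, limma adjusted p = 0.013) and miR-1a-3p (3.94 ± 1.17, limma adjusted p = 0.011) were higher too, with miR-1a-3p at 13181 ± 4398 in iBAT and 829.8 ± 31.7 in eWAT (SD, n = 3 each).

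Toward eWAT, among miRNAs of above-median abundance whose groups do not overlap, the epithelial miR-200b-3p (-9.48 ± 1.54, limma adjusted p = 0.00011) and miR-200a-3p (-7.97 ± 1.31, limma adjusted p = 0.00012) differed most. With 1 library left out the value of miR-200b-3p ranged from -10.54 to -8.96. miR-200b-3p stood at 2.64 ± 4.58 in iBAT and 1633 ± 761 in eWAT (SD, n = 3 each). miR-196b-5p, from the Hoxa cluster (Mir196b, GRCm38 chromosome 6, 52230081 to 52230165), had a log2 fold change of -4.13 ± 0.41 (limma adjusted p = 7.2e-07). miR-335-3p (-3.30 ± 0.27) and miR-335-5p (-2.52 ± 0.24) were both lower in iBAT, the latter at 2716 ± 304 against 15703 ± 2802 (SD, n = 3 each; limma adjusted p = 4.1e-07). miR-130a-3p (-2.88 ± 0.15, limma adjusted p = 3.4e-10) and miR-21a-3p (-2.82 ± 0.28, limma adjusted p = 7.2e-07) were lower as well. The value of miR-196a-5p was 0 in the iBAT libraries, and counted from a floor of 3 reads per library it was at least 5.12-fold higher in eWAT.

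miRNAs described in brown fat were higher in iBAT as a list, 15 of 16 with none lower and a median log2 fold change of 1.75 (limma camera, adjusted p = 6.03e-10; adjusted p = 0.00815 with an estimated correlation; fry adjusted p = 1.29e-10). miR-193b-3p, described in brown fat differentiation, stood at 8846 ± 1695 against 715.3 ± 56.4 (SD, n = 3 each; log2 fold change 3.61 ± 0.17, limma adjusted p = 1e-10), and miR-203-3p at 10433 ± 689 against 2397 ± 199 (SD, n = 3 each; 2.12 ± 0.12, limma adjusted p = 1.5e-09). All 6 tested muscle miRNAs were higher in iBAT beside them (median 3.96, limma camera adjusted p = 0.0641; adjusted p = 0.52 with an estimated correlation; fry adjusted p = 0.00537), including miR-499-5p (2.30 ± 0.59), miR-133a-5p (4.33 ± 1.23) and miR-206-3p (5.29 ± 1.50). The miR-30 family was higher in 4 of 5 members (median 1.01, limma camera adjusted p = 0.00425; adjusted p = 0.407 with an estimated correlation; fry adjusted p = 7.05e-07). Besides miR-30e-5p, its members miR-30c-5p (1.37 ± 0.14), miR-30b-5p (1.01 ± 0.14) and miR-30d-5p (0.84 ± 0.09) were higher, miR-30d-5p losing its call under quantile normalization (limma adjusted p = 0.0534). Abundant miR-30a-5p (0.05) was not called. It turned to -0.19 under total scaling, to -0.40 and a call toward eWAT with the 5 most abundant left out (limma adjusted p = 0.0173), and to -0.03 without iBAT 1.

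The miR-29 family, whose described targets include collagens and other matrix genes, was modestly higher in iBAT. miR-29a-3p reached 62006 ± 3074 against 42771 ± 2919, miR-29b-3p 872.2 ± 77.6 against 582.1 ± 62.5, and miR-29c-3p 960.4 ± 96.9 against 533.0 ± 33.9 (SD, n = 3 each). Log2 fold changes were 0.54 ± 0.13 (limma adjusted p = 0.0027), 0.58 ± 0.17 (0.011) and 0.85 ± 0.18 (0.00088). All 3 stayed above 0 under each scaling, and the calls depended on it. For miR-29a-3p the limma adjusted p was 0.699 with quantile normalization, 0.0865 with total scaling and 0.571 without the 5 most abundant miRNAs in the totals. For miR-29b-3p it was 0.141 with total scaling and 0.540 without those 5, and for miR-29c-3p 0.0702 without those 5. As a list the family did not pass camera (adjusted p = 0.10; adjusted p = 0.52 with an estimated correlation) and passed fry (adjusted p = 0.00325), and its members share sequence.

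Lists of Hox-cluster, immune and mesenchymal miRNAs leaned toward eWAT without passing camera. Hox-cluster miRNAs were lower in iBAT in 5 of 7 cases (median -0.80, limma camera adjusted p = 0.0641; adjusted p = 0.407 with an estimated correlation; fry adjusted p = 5.51e-07), with miR-10b-3p at -1.48 ± 0.22. Immune-cell miRNAs were lower in 4 of 10 cases and higher in 1 (median -0.64, limma camera adjusted p = 0.21; fry adjusted p = 0.00822). They included the myeloid miR-223-3p, at 345.7 ± 56.6 in iBAT against 898.8 ± 31.8 in eWAT (SD, n = 3 each; -1.39 ± 0.16, limma adjusted p = 3.9e-06), miR-223-5p (-3.64 ± 0.61, from -4.49 to -2.57 with 1 library left out) and miR-511-3p (-1.83 ± 0.33). The higher member was the lymphocyte miR-150-5p (1.04 ± 0.43, limma adjusted p = 0.049), against the direction of the lymphocyte genes. Mesenchymal and smooth muscle miRNAs had 5 lower and 1 higher of 10 (median -0.58, limma camera adjusted p = 0.214; fry adjusted p = 0.00537), with miR-145a-5p (-0.80 ± 0.14) and miR-143-3p (-0.63 ± 0.12, limma adjusted p = 0.00064) lower and miR-140-5p higher (1.06 ± 0.14). Epithelial miRNAs split, 4 higher and 6 lower of 11 (median -5.60, limma camera adjusted p = 0.894; fry adjusted p = 0.519 with the direction reversed). The 4 higher members included miR-182-5p, miR-183-5p and miR-203-3p, and beside this list 15 of 19 epididymis markers were lower in iBAT in the authors' deposited table.

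Endothelial miR-126a-3p, the most abundant miRNA of iBAT, stood at 260470 ± 12221 against 153850 ± 16552 in eWAT (SD, n = 3 each; 0.76 ± 0.13, limma adjusted p = 0.00013). Its partner strand miR-126a-5p changed by 0.88 ± 0.18 (limma adjusted p = 0.00072). Both calls were lost without the 5 most abundant miRNAs in the totals (limma adjusted p = 0.0731 and 0.0726), and that of miR-126a-5p also under quantile normalization (0.134). Red blood cell miRNAs were higher in 3 of 4 cases (median 0.90, limma camera adjusted p = 0.10; adjusted p = 0.52 with an estimated correlation; fry adjusted p = 0.00537): miR-144-5p at 0.97, miR-144-3p at 0.83 and miR-451a at 0.77, the latter 2 not called under total scaling and all 3 not called when the 5 most abundant were left out as well. The call of miR-451a was also lost without eWAT 3 (limma adjusted p = 0.0537).

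The remaining lists did not pass camera. miRNAs described as opposing browning had 3 higher and 2 lower of 9 (limma camera adjusted p = 0.505), with miR-27b-3p higher (0.92 ± 0.11, limma adjusted p = 7.9e-06) and miR-125b-5p lower (-0.72 ± 0.20, limma adjusted p = 0.0076, lost under median centring). The other higher members, miR-133a-3p (3.98 ± 1.22) among them, also belong to the muscle list. The let-7 family had 2 higher and 4 lower of 9 (median -0.23, limma camera adjusted p = 0.485), where let-7e-5p (-1.03 ± 0.11) and let-7i-5p (-0.83 ± 0.13) were lower and let-7g-5p higher (0.52 ± 0.12, limma adjusted p = 0.0014, lost under quantile normalization and both total scalings). The miR-17-92 and related clusters had 4 higher and 2 lower of 12, with a median of 0.07, a mean of -0.28 and an upward test (limma camera adjusted p = 0.473). miR-20a-5p (0.81 ± 0.13) and miR-92a-3p (0.79 ± 0.16) were higher, both lost without the 5 most abundant in the totals. The value of miR-20b-5p was 0 in iBAT, and it was at least 1.67-fold higher in eWAT. Of 41 tested miRNAs of the imprinted Dlk1-Dio3 cluster 2 were higher and 6 lower (limma camera adjusted p = 0.894), with miR-154-5p at 0.88 ± 0.22, miR-381-3p at 0.36 ± 0.13 and miR-667-3p at -1.43 ± 0.44. The call of miR-154-5p was lost without the 5 most abundant miRNAs in the totals (limma adjusted p = 0.125). That of miR-381-3p was lost under total scaling (0.463) and without iBAT 2 (0.0607), iBAT 3 (0.0808) or eWAT 3 (0.0809), and its sign turned to -0.08 without the 5 most abundant. That of miR-667-3p was lost with edgeR (0.0535), DESeq2 (0.0656), without iBAT 3 (0.0662) and without eWAT 2 (0.0517). Liver and nerve miRNAs were higher in 3 of 4 cases (median 1.49, limma camera adjusted p = 0.10; adjusted p = 0.407 with an estimated correlation; fry adjusted p = 5.51e-07), namely miR-9-5p (1.99 ± 0.23), miR-9-3p (2.19 ± 0.25) and miR-128-3p (0.99 ± 0.27). Counts adjusted over the list alone equalled those above in 10 of 15 lists. In the other 5 lists, the counts adjusted over the list alone were 0 higher and 4 lower (immune), 4 and 0 (red blood cell), 4 and 7 (epithelial), 5 and 2 (miR-17-92), and 0 and 0 (Dlk1-Dio3).

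Across all 6 depots, iBAT stood furthest apart. miR-30e-5p ranged from 29044 ± 1720 in mWAT to 44894 ± 2995 in cWAT among the white depots (SD, n = 3 each), all far below its 222340 in iBAT. miR-378a-3p ranged from 13717 ± 736 in mWAT to 28609 ± 4756 in cWAT (SD, n = 3 each) against 225950 in iBAT. miR-107-3p, from an intron of the pantothenate kinase gene Pank1, held 3175 ± 511 in iBAT and 297.6 ± 31.1 to 474.4 ± 57.5 in the white depots (SD, n = 3 each), and miR-30e-3p 4911 ± 229 against 877.2 ± 73.1 to 1241 ± 61.7. In the test over all depots 324 of 436 miRNAs (74.3%) differed (limma), with smallest p among those of above-median abundance for miR-30e-5p, miR-193b-3p, miR-196b-5p, miR-107-3p, miR-378a-3p and miR-30e-3p (limma adjusted p from 4.84e-10 to 4.32e-09).

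Against every one of the 5 white depots, 128 miRNAs differed from iBAT in 1 direction, 55 higher and 73 lower. Independent lists of the same sizes would share 0.3 higher and 1.1 lower, and libraries simulated with no effect gave a mean of 0.01 and at most 1 in 100 simulations. Neither number is a reference for depots that differ. The 5 comparisons share the iBAT libraries, which raises the overlap, and the simulation held no difference between any depots. The smallest of the 5 log2 fold changes was 3.70 for miR-182-5p, 2.99 for miR-378a-3p, 2.74 for miR-107-3p, 2.31 for miR-30e-5p, 2.22 for miR-193b-3p, 0.85 for miR-29c-3p, 0.58 for miR-29b-3p and 0.54 for miR-29a-3p. The split of 55 and 73 holds for the authors' size factors. For the miR-29 members the call against eWAT depended on the scaling, as given above, and so does their place among the 55. Numbers of miRNAs called between iBAT and a white depot ran from 207 (cWAT; 86 higher in iBAT, 121 lower) through 232 (aWAT; 97 and 135), 237 (iWAT; 107 and 130) and 240 (eWAT) to 242 (mWAT; 94 and 148).

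**Figure D2:**
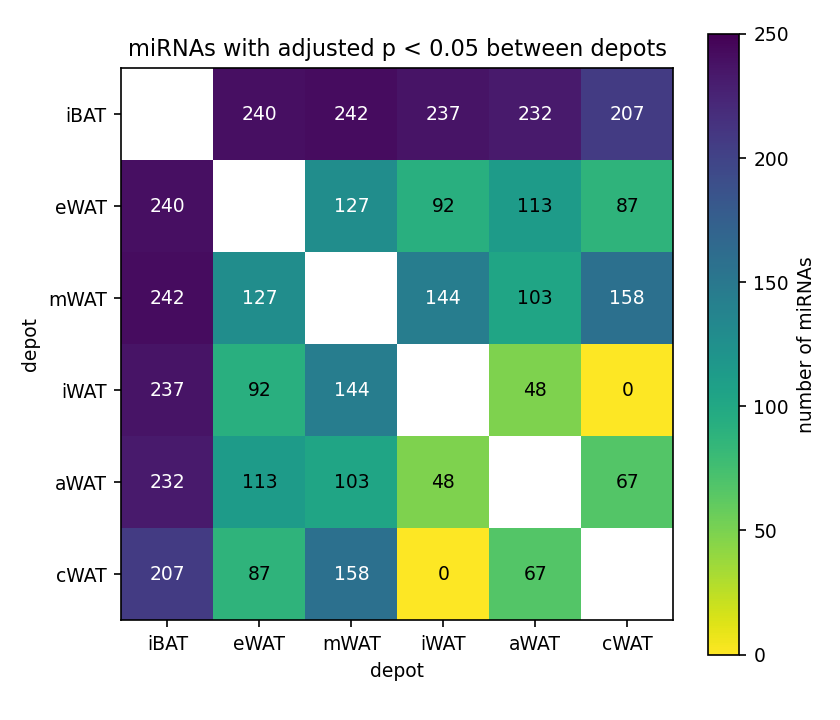
The matrix gives the number of 436 tested miRNAs with a limma adjusted p under 0.05 for each pair of the 6 depots. Pairs with iBAT hold 207 to 242, pairs of white depots 0 to 158.

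White depots differed in the Hox-cluster miR-196, in miR-143 and miR-145 and in miR-335, among others. miR-196a-5p stood at 1160 ± 72.3 in iWAT, 1152 ± 110 in cWAT and 614.5 ± 46.8 in mWAT, but at 25.8 ± 6.20 in eWAT and 6.62 ± 2.28 in aWAT (SD, n = 3 each; iWAT over aWAT 7.29 ± 0.20 on the log2 scale, limma adjusted p = 2.26e-13). Against the floor of 3 reads per library in iBAT it was at least 230-fold higher in iWAT, 228-fold in cWAT, 122-fold in mWAT and 1.31-fold in aWAT. Its genes lie in the Hox clusters on GRCm38 chromosomes 11 (Mir196a-1, 96265164 to 96265265) and 15 (Mir196a-2, 102973350 to 102973434). miR-196b-5p followed, with 2156 ± 153 in mWAT, 1345 ± 164 in iWAT and 1062 ± 142 in cWAT against 100.7 ± 65.4 in aWAT and 83.2 ± 26.4 in eWAT (SD, n = 3 each), and the 2 miRNAs may share reads.

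miR-143-3p, abundant in smooth muscle and mesenchymal cells, took 26.65% of normalized counts in mWAT, at 782080 ± 136520 against 294480 ± 3099 in aWAT to 347590 ± 40265 in eWAT (SD, n = 3 each; mWAT over iWAT 1.36 ± 0.12, limma adjusted p = 7.43e-06). The call was lost under quantile normalization, which gives the most abundant miRNA of each library the same value. Its cluster partner miR-145a-5p was higher in mWAT under every scaling tried, at 49266 ± 11848 against 17112 ± 1253 in cWAT to 21045 ± 1548 in iWAT (SD, n = 3 each; mWAT over iWAT 1.2 ± 0.14, limma adjusted p = 1.66e-05, at most 0.00149 under the 4 other scalings). miR-335-5p was higher in eWAT, at 15703 ± 2802, than in the other white depots, where it held 2234 ± 878 in aWAT to 3439 ± 201 in mWAT (SD, n = 3 each; eWAT over mWAT 2.18 ± 0.24, limma adjusted p = 4.77e-06). miR-34c-5p was likewise highest in eWAT, with 405.2 ± 121 in mWAT to 835.0 ± 352 in aWAT elsewhere (SD, n = 3 each; eWAT over aWAT 3.18 ± 0.39, limma adjusted p = 2.82e-05).

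miR-1a-3p was the second most abundant miRNA of aWAT, at 211700 ± 201990 (SD, n = 3), a spread as large as its mean. That rank rests on aWAT 1 (440918.8), as it held 134457 in aWAT 2 and 59728.3 in aWAT 3, the latter below miR-10a-5p (72618.4). It was called higher there than in each other white depot, by 7.52 ± 1.17 over eWAT (limma adjusted p = 0.000312), but the call against cWAT (0.030) was lost without cWAT 1 (0.109). The muscle miRNA miR-206-3p was also highest in aWAT, at 2494 ± 1491 (SD, n = 3). Among the white depots, eWAT differed from mWAT in 127 miRNAs, from iWAT in 92, from aWAT in 113 and from cWAT in 87. mWAT differed from iWAT in 144, from aWAT in 103 and from cWAT in 158, and aWAT differed from iWAT in 48 and from cWAT in 67. The count of eWAT against iWAT fell to 54 without iWAT 2, 57 without eWAT 1 and 58 without eWAT 3, and that of eWAT against aWAT to 75 without eWAT 1 and 74 without eWAT 3. For eWAT against cWAT it was 55 without cWAT 2 and 54 without eWAT 3, and for iWAT against aWAT 28, 26 and 27 without iWAT 1, iWAT 2 and aWAT 2. For aWAT against cWAT it was 33, 22, 42, 43 and 11 without cWAT 1, cWAT 2, cWAT 3, aWAT 1 and aWAT 2.

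Some cell-type miRNAs were uneven between libraries of 1 depot. miR-1a-3p ranged from 59728.3 in aWAT 3 to 440918.8 normalized counts in aWAT 1, where it took 15.3% of reads, and from 378.4 in iWAT 2 to 16537.3 in iWAT 1. miR-192-5p, abundant in gut epithelium, stood at 17664.8 in mWAT 2 and at 1509.4 and 1682.5 in the other mWAT libraries. The lymphocyte miRNA miR-150-5p stood at 12728.1 in cWAT 2 and 2500 in cWAT 1. miR-34c-5p, miR-375-3p and miR-200b-3p were lower in eWAT 2 (3956.6, 198.7 and 771.4) than in eWAT 1 (8182.7, 477.9 and 1913) and eWAT 3 (10924.3, 517.1 and 2214.3). Over the 18 libraries, the median SD within depots was 1.66 on the log2 scale for the muscle list and 1.86 for the epithelial list. Random lists of the same size and abundance had a central 95% that ended at 0.65 and 0.45.

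**Figure D3:**
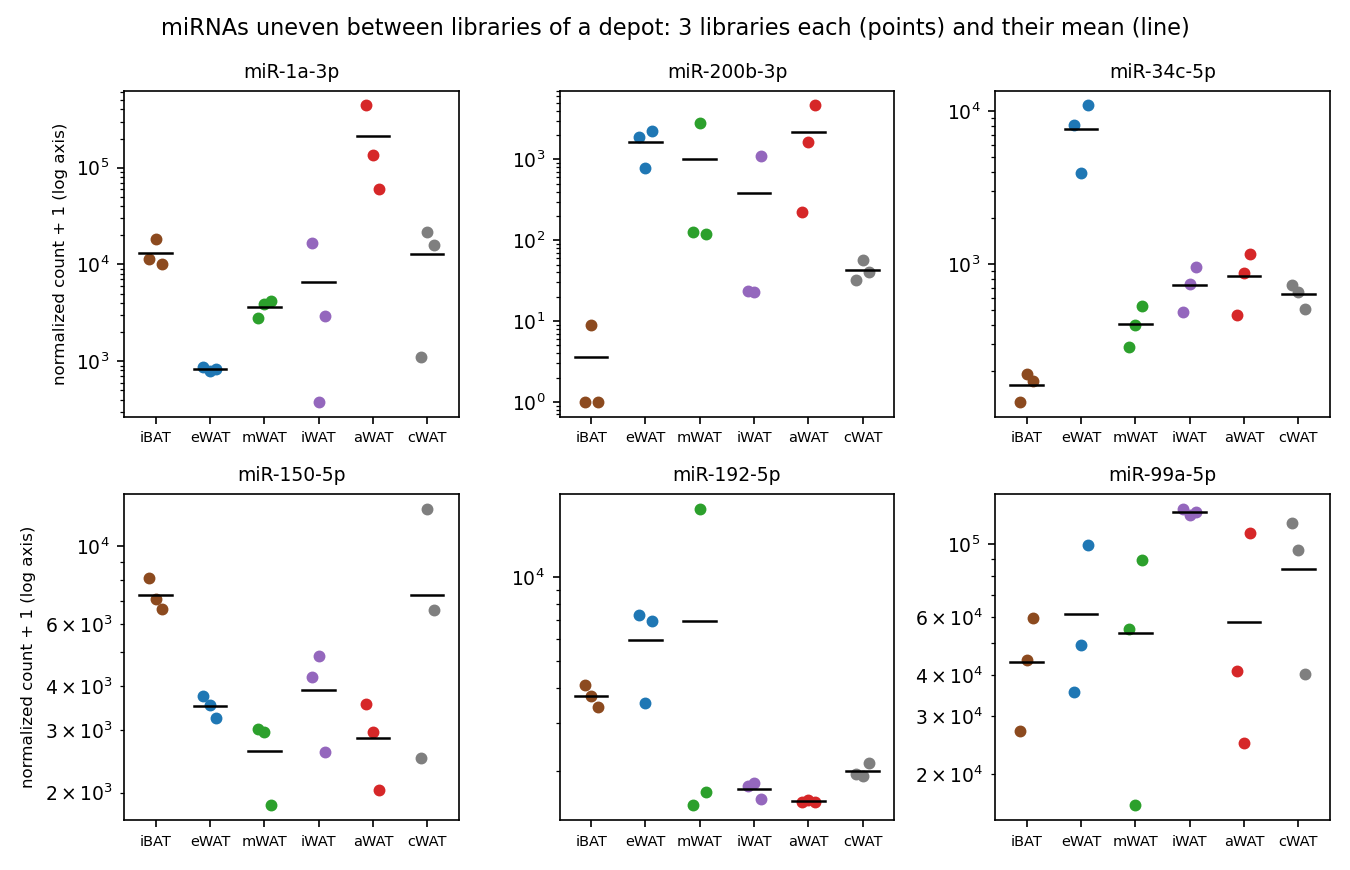
Normalized counts + 1 (log axis) of 6 miRNAs in the 3 libraries of each depot, with the mean as a line. The libraries of 1 depot differ widely, as for miR-1a-3p in aWAT (59728.3 to 440918.8) and miR-192-5p in mWAT (1509.4 to 17664.8).

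**Figure D4:**
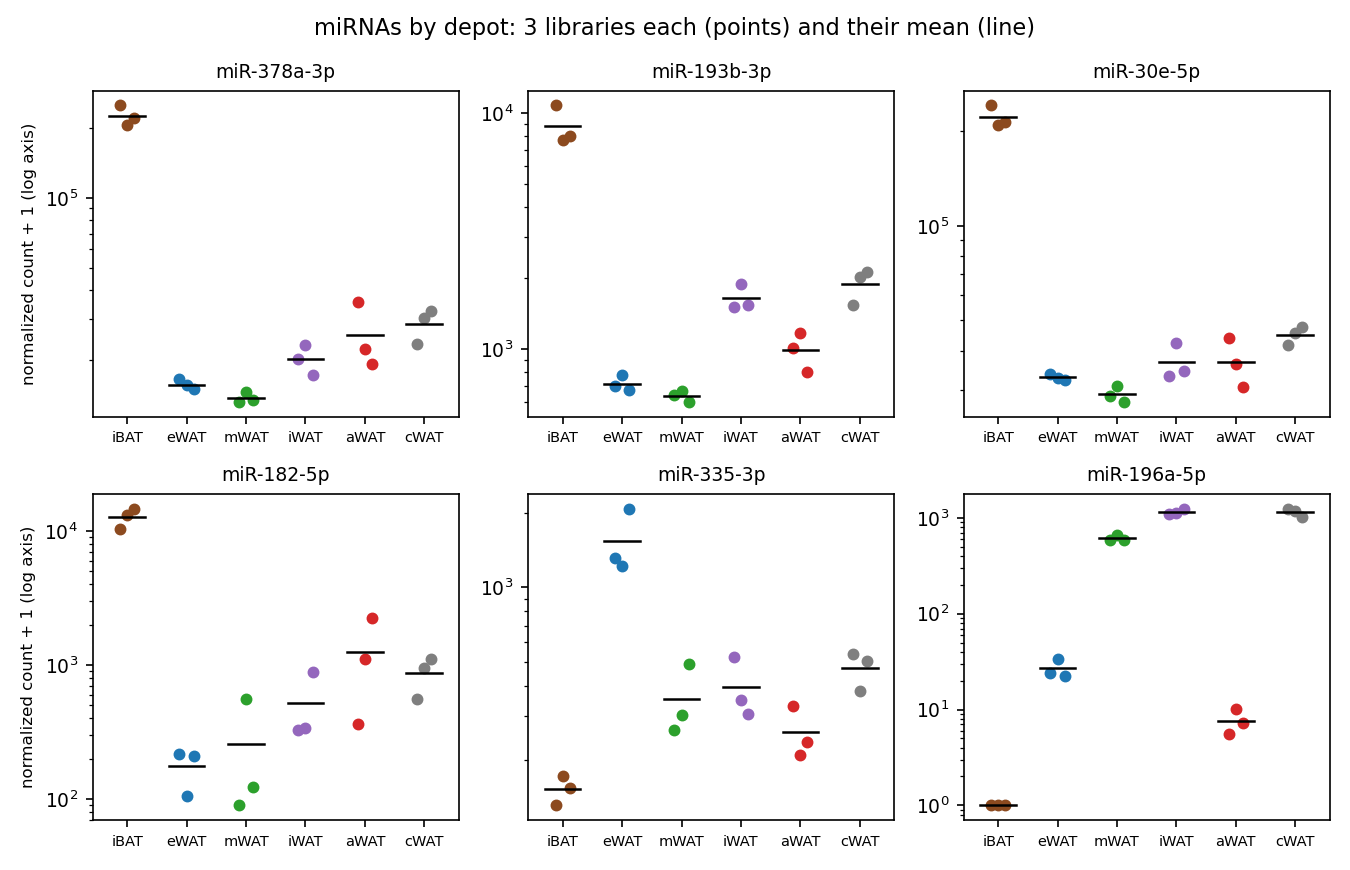
Normalized counts + 1 (log axis) of 6 miRNAs in the 3 libraries of each depot, with the mean as a line. miR-378a-3p, miR-193b-3p, miR-30e-5p and miR-182-5p are highest in iBAT (225950, 8846, 222340 and 12729 on average), while miR-335-3p is highest in eWAT (1540) and miR-196a-5p is at 0 in iBAT.

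The groups labelled cWAT and iWAT had the fewest calls of all pairs. If cWAT is inguinal fat of cold-housed mice, this pair compares housing temperatures in 1 depot, which the labels do not settle. limma called 0 miRNAs between them, with 54 at an unadjusted p under 0.05, edgeR called 1 (59 unadjusted) and DESeq2 12 (58 unadjusted). For this pair the authors' deposited table had 13 miRNAs with an adjusted p under 0.05 and no adjusted p for 246. The limma count was 4 without cWAT 1, 4 without aWAT 1 and 2 without aWAT 3. The smallest p belonged to miR-27a-3p, at 24990 ± 1446 in iWAT and 18010 ± 1155 in cWAT (SD, n = 3 each; log2 fold change of cWAT over iWAT -0.47 ± 0.10, limma adjusted p = 0.0546, edgeR adjusted p = 0.0409). In the authors' deposited table the adjusted p of miR-27a-3p was 0.000102. miR-125b-2-3p held 1219 ± 56.4 in iWAT and 904.9 ± 95.4 in cWAT (SD, n = 3 each; -0.43 ± 0.09, limma adjusted p = 0.0546). miR-25-3p (0.42 ± 0.10), miR-15b-3p (0.87 ± 0.21) and miR-497a-5p (-0.60 ± 0.15) followed, each with a limma adjusted p of 0.0857. DESeq2 called each of these miRNAs, with adjusted p from 0.000313 (miR-27a-3p and miR-125b-2-3p) to 0.00574 (miR-497a-5p). In the authors' deposited table they had an adjusted p of 0.000102 to 0.00412.

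Each depot had its own order of abundant miRNAs. miR-143-3p led the 5 white depots, with 11.82% of normalized counts in aWAT to 26.65% in mWAT, and stood behind miR-126a-3p (8.72%) and miR-378a-3p (7.56%) in iBAT, ahead of miR-30e-5p (7.44%) and miR-26a-5p (4.91%). The 5 most abundant miRNAs of every white depot included miR-126a-3p, miR-26a-5p and miR-10b-5p, the latter at 10.44% in mWAT. The remaining member of the 5 was miR-30a-5p in eWAT, miR-10a-5p in mWAT and cWAT, miR-99a-5p in iWAT and, through aWAT 1, miR-1a-3p in aWAT. Between iBAT and eWAT miR-10b-5p was lower in iBAT (-0.80 ± 0.20, limma adjusted p = 0.0032), while miR-26a-5p (-0.15), miR-10a-5p (0.14) and miR-99a-5p (-0.43 ± 0.63) were not called. miR-26a-5p was called lower under quantile normalization, total scaling and total scaling without the 5 most abundant (limma adjusted p = 0.0228, 0.00148 and 0.000712), and miR-10a-5p turned to -0.06, -0.11 and -0.31 under these.

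Mature miRNAs and the genes they lie in were compared between iBAT and eWAT. Ppargc1b, a coactivator of mitochondrial genes (GRCm38 chromosome 18, 61291445 to 61400756), contains Mir378a (61397835 to 61397900) and was higher in iBAT at 4.93 (adjusted p = 4.69e-122) in the authors' deposited table, beside 3.85 for miR-378a-3p. The imprinted gene Mest (chromosome 6, 30733506 to 30748466), which contains Mir335 (30741299 to 30741396), was lower at -3.19 (adjusted p = 6.95e-13) in the authors' deposited table, beside -3.30 for miR-335-3p. Pank1 (chromosome 19, 34806935 to 34883423), which contains Mir107 (34820687 to 34820773), was at 5.65 (adjusted p = 4.26e-34), and Nfyc (chromosome 4, 120757435 to 120831579), which contains Mir30e (120772606 to 120772697), at 1.47 (adjusted p = 3.09e-24) in the authors' deposited table. The collagen gene Col27a1 (chromosome 4, 63214009 to 63334991), which contains Mir455 (63256851 to 63256932), was at 3.33 (adjusted p = 6.6e-19) in the authors' deposited table, beside 3.24 for miR-455-3p and 3.71 for miR-455-5p.

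Over 38 host genes, with 1 value per gene from 57 pairs, the log2 fold changes correlated with Pearson's r = 0.74 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 2e-05) and Spearman's rho = 0.62 (permutation p = 9e-05, adjusted p = 9e-05), the 2 correlations forming the family. These are correlations across genes, which are not independent replicates, between tests from different samples. Without the 2 host genes farthest from the median r was 0.61. The sign was the same for 28 of 38 genes. Both strands of a miRNA gene, such as Mir335 or Mir378a, count as separate pairs with 1 host value. Counted so, 18 of 20 pairs with both members called went the same way. The exceptions were miR-582-3p (-1.38) with Pde4d (4.42) and miR-140-5p (1.06) with Wwp2 (-0.40), host values being from the authors' deposited table. The endothelial gene Egfl7, which contains Mir126a, was not called (-0.37, adjusted p = 0.30) in the authors' deposited table.

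**Figure D5:**
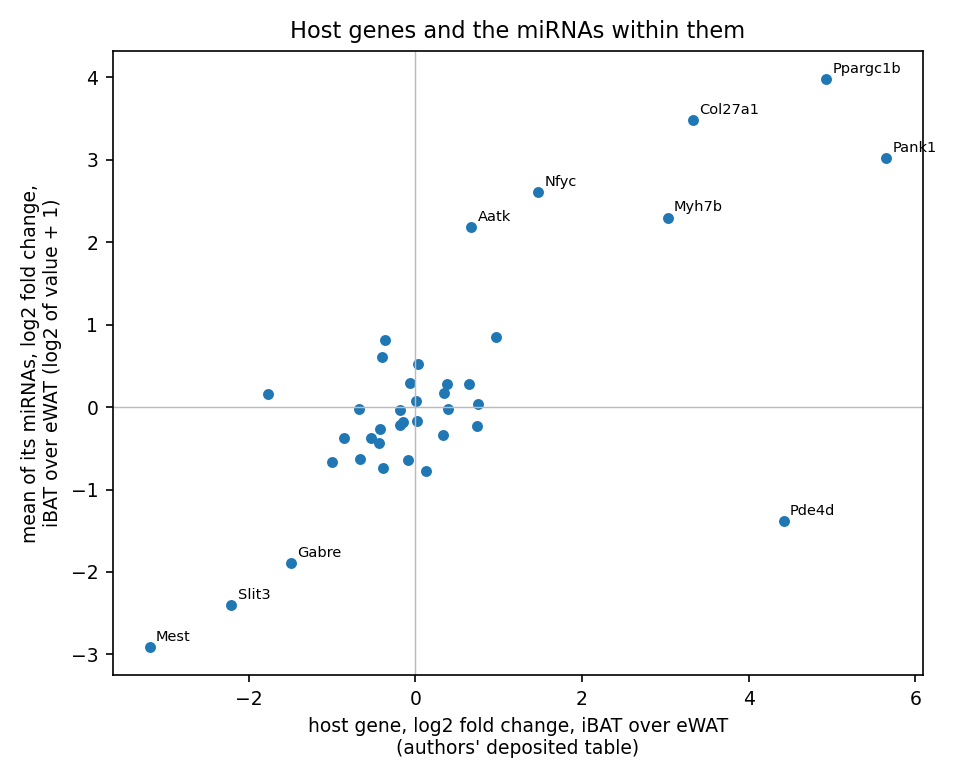
Each of the 38 points is a host gene, with its log2 fold change of iBAT over eWAT in the authors' deposited table on the x axis and the mean log2 fold change of its miRNAs on the y axis. The points rise together (Pearson's r = 0.74), and 28 of 38 lie in the quadrants of equal sign.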

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

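edgeR and DESeq2 on recovered reads, the joint removal of iWAT 3 and cWAT 2, and the mRNA alternatives other than the base mean filter were chosen after the results were seen; the rest were planned. Of the results that answer a comparison, 660 values stayed within a set margin of the main value and 50 moved beyond it. Values within the margin need not equal the main value. For counts the margin is the one given below with the replicate block. Of values of named genes and miRNAs 2699 kept direction and side of the threshold, 69 lost the call, 4 gained it and 15 changed sign. Requiring a 2-fold change (treat) cut counts, by its construction: iBAT against eWAT 67 (31 higher, 36 lower), mWAT 56, iWAT 43, aWAT 58 and cWAT 42; eWAT against mWAT 26, iWAT 15, aWAT 24 and cWAT 22; mWAT against iWAT 4, aWAT 4 and cWAT 0; aWAT against iWAT 8 and cWAT 3; apart in iBAT 23. For iWAT against cWAT, quantile normalization called 4, median centring 3, total scaling 1, edgeR 1 and DESeq2 12. For aWAT against cWAT, no trend gave 43, total scaling 44 and removal of iWAT 3 with cWAT 2 26. Without the 5 most abundant in the totals 58 were higher and 194 lower in iBAT than eWAT (23% higher), while median centring gave 55.5% higher. Lists past the test numbered 5 under each total scaling, 1 with an estimated correlation and 9 with fry. mRNA genes with a log2 fold change of at least 1 numbered 5790; the other mRNA alternatives gave 8107 to 9085 genes. Apart from these constructions, the cause was not tested.

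Changed signs (log2, iBAT over eWAT) were: under quantile normalization miR-25-3p -0.055, miR-15b-3p 0.07, miR-30a-5p -0.185 and miR-10a-5p -0.058; under median centring miR-15b-3p 0.052; under total scaling miR-27a-3p -0.178, miR-25-3p -0.039, miR-30a-5p -0.194 and miR-10a-5p -0.106. Without the 5 most abundant they were miR-381-3p -0.081, miR-27a-3p -0.384, miR-25-3p -0.245, miR-30a-5p -0.401 and miR-10a-5p -0.312. With 1 library left out miR-30a-5p ranged from -0.031 (without iBAT 1) to 0.09 (without eWAT 1). The cause was not tested.

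Leaving out 1 library gave 299 to 330 over all depots, 97 to 124 apart in iBAT, 199 to 245 for iBAT against eWAT (96 to 114 higher, 103 to 131 lower), 204 to 244 against mWAT, 197 to 249 against iWAT, 205 to 237 against aWAT and 167 to 213 against cWAT. For eWAT it gave 100 to 145 against mWAT, 54 to 103 against iWAT, 74 to 123 against aWAT and 54 to 110 against cWAT. For mWAT it gave 108 to 153 against iWAT, 74 to 114 against aWAT and 113 to 170 against cWAT, for iWAT 26 to 55 against aWAT and 0 to 4 against cWAT, for aWAT 11 to 67 against cWAT, and 2 to 3 lists. Between iBAT and eWAT the named calls lost were miR-451a, miR-667-3p and miR-381-3p; between white depots 81 of 215 named calls were lost without 1 library or another, and the cause was not tested.

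With the replicate number as a block, 247 miRNAs were called for iBAT against eWAT (edgeR 236), 319 over all depots, 133 apart in iBAT and 0 for iWAT against cWAT, and no count moved by over 1.5 times. Only 11 of 45 same-number pairs of libraries had deviations correlated over 0.1 (-0.36 to 0.51, median 0.01), and 5 of 18 libraries correlated best with their own number. No paired analysis was possible because the mRNA file gives comparisons without libraries; for the same reason DESeq2, other size factors, library size scaling, pseudocounts, trend, treat, the block, left-out libraries, the 10 most abundant genes left out of totals, estimated correlation and fry were not run on mRNA, nor the seed site test. A depth of 1293407 reads in iBAT 1 limits scarce miRNAs, for which 3 reads there equal 7.22 normalized counts.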

Other observations

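All tests in this part were chosen after the results they bear on were seen, as were the single miRNAs outside the naming rule. Gut and blood miRNAs marked single libraries. mWAT 2 held 742.3 normalized counts of miR-194-5p and 2147 of miR-215-5p, beside 102.3 and 12.8 in mWAT 1 and 95 and 5.4 in mWAT 3, and these epithelial miRNAs accompany miR-192-5p in the intestine. miR-375-3p was at 583.9 in mWAT 2, 0 in mWAT 1 and 6.5 in mWAT 3. In cWAT 2 the leukocyte miR-142a-3p reached 5074.2, against 1068.8 in cWAT 1 and 2308.7 in cWAT 3. The immune list had a median SD of 0.77 within cWAT and 0.14 within iBAT on the log2 scale.

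miR-21a-5p, among the most abundant miRNAs of many tissues, was one of 73 miRNAs lower in iBAT than in each white depot, by 2.28 to 2.98 on the log2 scale. Others of above-median abundance were miR-130a-3p (1.75 to 2.88), miR-218-5p (1.44 to 2.53), miR-221-3p (1.34 to 1.43) and its cluster partner miR-222-3p (1.27 to 1.66), sizes being those of the fall in iBAT. By distance to depot means made without the library itself, over 419 miRNAs outside the muscle and epithelial lists, 16 of 18 libraries lay nearest to their own depot, the exceptions being iWAT 2, nearest to cWAT, and cWAT 1, nearest to iWAT. The main axis of variation (36.9%) set the iBAT libraries (-21.80 to -27.11) apart from the rest (-2.71 and above).

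Muscle signal was higher in iBAT than in eWAT, with 22 of 22 muscle markers higher in the authors' deposited table, Myh4 among them at 17.69. This count is the pattern itself, and by it skeletal muscle carried with the interscapular pads and expression by brown adipocytes cannot be told apart. Unequal carryover predicts uneven muscle miRNAs, and their median SD within iBAT, 0.51 on the log2 scale, lay just above the central 95% of random lists, which ended at 0.50; it was larger in iWAT (2.63), cWAT (2.63) and aWAT (1.45), so unevenness is not special to iBAT. Both explanations stay open, that of brown adipocytes, which share a lineage with muscle, as untested. How far the brown adipocyte list and the mitochondrial lists, whose genes muscle also uses, share in this was not tested.

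Epididymal and epithelial signal was higher in eWAT, with 15 of 19 epididymis markers lower in iBAT in the authors' deposited table, Crisp1 at -14.34 and Lcn5 at -17.81 among them. This count is the pattern itself, and by it epididymal duct carried with the pads cannot be told apart from a depot difference. The 6 epithelial miRNAs lower in iBAT had a median SD of 0.81 within eWAT, where the central 95% of random lists ended at 0.41. Unequal amounts of epithelium predict this, but the 6 were picked from these same data. Their SD was larger in mWAT (2.68), iWAT (2.88) and aWAT (2.06). In cWAT it was 0.44, inside the random range, which ended at 0.66. Within iBAT, where they were lower, it was 0.66 and also above the random range, which ended at 0.57. The spread therefore cannot show its source. On average miR-200b-3p was as high in aWAT (2179 ± 2268, SD, n = 3) as in eWAT, so epididymis is not the sole possible source of it. That aWAT mean is below its own SD. The mean of the epithelial list ran from 6.92 in aWAT 1 to 10.18 in aWAT 3 on the log2 scale. A depot difference in epithelial or mesothelial cells was not tested and stays open.

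miR-99a-5p was uneven within depots, with an SD of 0.85 on the log2 scale against a median of 0.20 over above-median miRNAs, and ranged from 16089.7 in mWAT 2 to 89720.5 in mWAT 3. Altered transcription of its locus (GRCm38 chromosome 16, Mir99a at 77598936 to 77599000) would carry miR-125b-2-3p of the same cluster (Mir125b-2 at 77646273 to 77646343). The slope of that miRNA on miR-99a-5p was -0.03. The cluster member let-7c-5p, which also has another locus, had a slope of 0.10 (r = 0.76, permutation p = 0.0093, adjusted p = 0.015). These members differed, so the values argue only against an equal change of the whole cluster, and altered transcription of part of it stays open. Deviations from depot means followed miR-362-5p, encoded on chromosome X and the strongest of 435 miRNAs screened (16 with r over 0.8, 4 under -0.8), over 18 libraries (Pearson's r = 0.98, permutation p = 3e-05, adjusted p = 0.00015; Spearman's rho = 0.97, permutation p = 0.00024, adjusted p = 0.0012; 5 relations, permuted within depots; r = 0.97 without the 2 farthest libraries), and opposed miR-10a-5p (r = -0.89, permutation p = 0.00049, adjusted p = 0.0012), both picked as the extremes of the screen, so that these p-values overstate the evidence. Sequencing depth cannot be told apart from other causes by its correlation of r = -0.10 (permutation p = 0.74, adjusted p = 0.74; rho = 0.06, permutation p = 0.82), as a low r sets no bound. A difference in library preparation may underlie it but no label gives a batch, and no biological explanation was tested.

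Regrouping the libraries bears on the counts of called miRNAs. Over all depots 1 of 100 groupings drawn, the real one, reached 324 calls (highest other 94). For miRNAs apart in iBAT 1 of 100, again the real one, reached 128 (highest other 0). A share of 1 in 100 is the smallest that 100 groupings can give, so chance is made unlikely for both and is not excluded. Each pair of depots has 10 splits, too few for a share under 0.05. The real value and the highest other were 240 and 0 for iBAT against eWAT, 242 and 0 against mWAT, 237 and 0 against iWAT, 232 and 0 against aWAT, and 207 and 0 against cWAT. For eWAT they were 127 and 2 against mWAT, 92 and 0 against iWAT, 113 and 1 against aWAT, and 87 and 0 against cWAT. For mWAT they were 144 and 0 against iWAT, 103 and 2 against aWAT, and 158 and 0 against cWAT, for iWAT 48 and 9 against aWAT, and for aWAT 67 and 2 against cWAT. For iWAT against cWAT the real value was 0, the highest other 4, and 10 of 10 splits reached the real value.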
